A study of Escherichia coli with 108 samples.

How the data were processed

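The series held RNA sequencing libraries and chromatin immunoprecipitation libraries of Lrp with their inputs. The 36 RNA libraries were analysed, and the 72 immunoprecipitation and input samples were not analysed here. Per the labels' protocols, cells were treated with RNAProtect, ribosomal RNA was depleted with Ribo-Zero and libraries were made with the NEBNext Ultra Directional kit. Per the submitters' processing notes, the tools were cutadapt 1.8.1, Trimmomatic 0.32, kallisto 0.43.0 and sleuth, for which no version was given in the sources used here. The transcript set, the genome build and the strand setting given to kallisto were not given in the sources used here. A gene that overlaps another or lies antisense to it is therefore uncertain.

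Each deposited file held, per the file headers, an estimated count and a TPM value for each of 4712 targets of 1 library. The authors' estimated counts (expected counts of kallisto) were used after rounding to whole numbers, and the deposited TPM values were not used in any test. The sleuth Wald test tables that the labels name were not used here. 343 targets held fractional counts in at least 1 library, which marks reads shared between targets, for example the near-identical gadA and gadB or argF and argI. Values of such genes are uncertain. Target names were matched to the gene table of assembly ASM584v2, in which 4314 matched a symbol, 149 a synonym and 249 neither. That table was used only for names, gene types and neighbours.

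Libraries were grouped by strain, medium and phase as the labels give them, and lrp was counted in each library before any comparison. The tests, the samples in each fit, 28 gene lists (515 distinct genes, 3 of them not tested) and the rule for genes named in the text were fixed before the data were examined. The lists came from textbook knowledge of E. coli and of Lrp.

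Differences were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test on all 36 libraries in 1 model of 18 groups, so that all groups shared an estimate of the spread with 18 residual degrees of freedom (prior degrees of freedom 4.48, common biological coefficient of variation 22.1%). Targets passed filterByExpr with a minimum count of 10, which kept 4320, and libraries were scaled by TMM. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, with 0.05 as the limit. The standard error (SE) given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is approximate where a group held few counts. Displayed log2 CPM values used a prior count of 3. The comparisons were mutant against wild type in each of 9 conditions and on their average, each medium against minimal medium in wild type within a phase, each later phase against log phase in wild type within a medium, the strain difference in each medium against that in minimal medium, and an F test of the strain difference over the 3 phases of a medium.

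Gene lists were tested with camera of limma 3.58.1 on the same model with a preset correlation of 0.01 between genes and again with a correlation estimated for each list, adjusted over the 28 lists of a comparison. Beside the count over all genes, a count adjusted over the list alone was made. The textbook list of Lrp targets shared 29 of its 33 measured genes with other lists.

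Genes were named by a fixed rule. lrp and its neighbours trxB and ftsK were taken everywhere. In each strain comparison the 6 highest and 6 lowest log2 fold changes were taken among called genes with both mutant libraries on the same side of both wild type libraries and a mean log2 CPM of at least 3, leaving out lrp and rRNA and tRNA genes. The average used 15 of each sign, the media and phase comparisons 6 of each sign, the interactions the 5 smallest p-values of each sign and the F tests the 8 smallest. Up to 4 called members of each list with the smallest p-values and all textbook targets were added, with 1 further member not called where a contrast was given. From this pool the text names those it describes. Where a group held 3 counts or fewer of a gene over its libraries, no fold is given except for lrp, whose lower bound was set against a floor of 3 counts in each mutant library.

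The tests were tried on simulated data, drawn for the real genes with the real library sizes and known changes. Mutant groups started from the wild type means of their condition. For the media and phase comparisons all groups started from the wild type minimal log means. Counts varied by a spread that depended on abundance only, without deviating libraries or correlation between genes, so recovery in the real data may be lower. The strain comparisons and the average had 200 changed genes each. For the 9 strain comparisons, run on 4303 genes, 33 to 58 of 100 genes changed 2-fold and 91 to 98 of 100 changed 4-fold were recovered, none in the wrong direction, and 4 to 9 unchanged genes were called. For the average, where each gene had the same change in all 9 conditions, 178 of 200 were recovered. That was 79 of 100 with a log2 change of 0.5 and 99 of 100 with a log2 change of 1. Recovery of changes that vary between conditions was not simulated for the average. Recovery was lower for the strain difference between media, with 380 to 392 changed genes, where 11.2% to 24.0% of 2-fold and 72.6% to 82.5% of 4-fold changes were found. The F tests found 52.5% to 55.5% of 566 to 568. In the media and phase comparisons 36.4% to 59.7% of 2-fold and 93.7% to 98.5% of 4-fold changes were found. A change of 2-fold in 1 condition, and more so a 2-fold difference between conditions, was therefore often below what 2 libraries per group could show.

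The alternatives were RLE size factors in place of TMM, no filter on low counts, removal of rRNA and tRNA genes, the Wald test of DESeq2 1.42.0, a fit of the compared groups alone, each library left out in turn, blocks by replicate number and by culture number (limma voom), an estimated correlation for lists, and adjustment over all 9 strain tests together. In place of the F tests DESeq2 used its likelihood ratio test. After the data were seen, 3 more were added: the culture number block for the average and the F tests, thinning every library at random to the total of the smallest, and leaving minimal transition and rich stationary out of the average, the union and the list count. Thinning was first done with thinCounts of edgeR. Its counts of called genes had been seen when its draws were found to vary more than random sampling allows (chi-square per gene 1.46 to 11.8 over libraries), and binomial draws replaced it (0.960 to 1.05). With 1 library of a group left out, the remaining library was taken to vary like the other groups. For the average test 99 random regroupings of the libraries within conditions were refitted beside the real one. Plots were made with matplotlib 3.10.9.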

Results

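RNA was measured in Escherichia coli K-12 MG1655, the wild type, and in a strain whose lrp gene carried a kanamycin resistance insertion (Lrp::kanR), called the mutant here. Lrp, the leucine-responsive regulatory protein, is known as a transcription regulator of amino acid metabolism, transport and surface structures. The series title gives the question as how much of the genome Lrp regulates. Per the labels, cultures grew with glycerol in MOPS minimal medium, in MOPS minimal medium with LIV (not spelled out in the labels) or in MOPS rich defined medium, and were harvested in logarithmic phase, at the transition point or in stationary phase. Each of the 18 groups of strain, medium and phase held 2 libraries, 36 in all. Total estimated counts per library ran from 808194 in wild type rich stationary replicate 1 to 10174789 in mutant LIV transition replicate 1, with a median of 3107177. The 10 most abundant targets held 11.3% to 33.6% of a library, and rRNA and tRNA genes 0.197% to 2.05%. Of 4712 targets, 4320 had enough counts to be tested. The labels give growth from a single colony and a number per library, taken here as that of its culture, and no more on how the cultures were started, so the p-values measure the spread between these libraries. By these numbers 10 cultures gave both a log and a stationary library, so libraries of those phases are not all independent. The fits took them as independent; the estimated correlation within a culture was 0.019.

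lrp itself was counted 183 to 5732 times in each wild type library. In 14 of the 18 mutant libraries it had 0 counts, and the other 4 held 1 or 2. The wild type lrp level was 691 ± 13.4 CPM (counts scaled by library total and TMM factor; SD, n = 2) in minimal log, 1107 ± 423 in minimal transition and 167 ± 22.3 in minimal stationary. In the 6 conditions where both mutant libraries had 0 counts, lrp was at least 151-fold lower (minimal stationary) to at least 1828-fold lower (LIV transition), against a floor of 3 counts per library that covers counting error only. ftsK, the DNA translocase gene next to lrp in assembly ASM584v2, was higher in the mutant by a log2 fold change of 1.05 ± 0.05 (SE) on average and was called in 7 of 9 conditions. trxB, the neighbour on the other side, stood at 0.34 ± 0.07. Replicate libraries of a group correlated with r of 0.920 (wild type rich stationary) to 0.994 (wild type LIV log) across genes, which are not independent of each other, so no pair was a duplicate, and their spread exceeded counting error in every group (chi-square per degree of freedom 6.11 to 151).

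**Figure D1:**
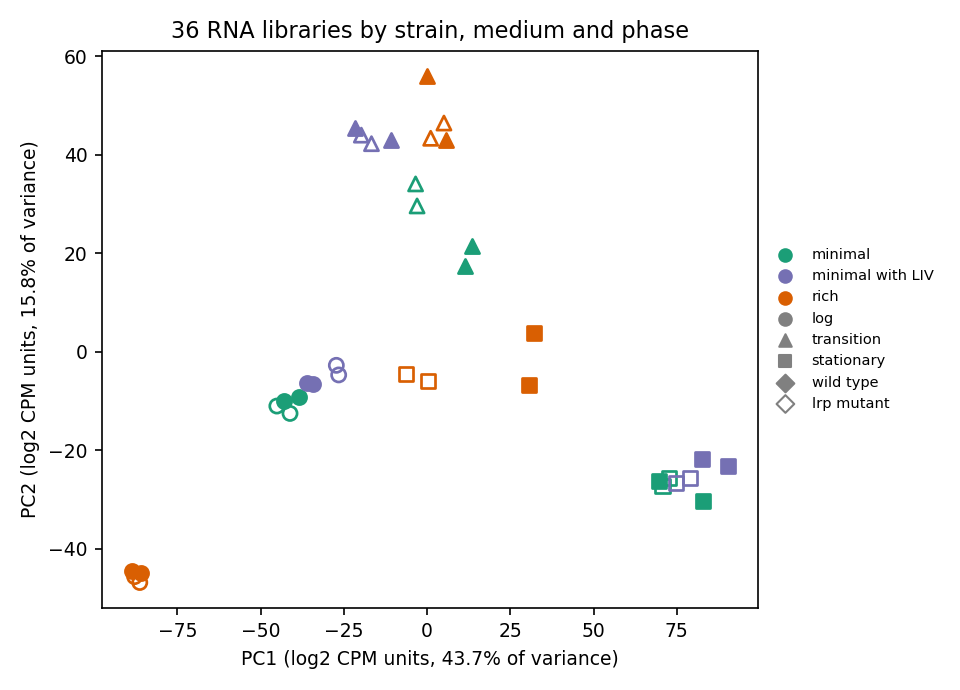
First and second principal components (log2 CPM units) of the 36 libraries, each point a library, coloured by medium, shaped by phase and filled for wild type. PC1 carried 43.7% of the variance and PC2 15.8%, and the strains lay apart mainly in minimal transition and rich stationary.

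Between 104 and 2047 genes differed between the strains in a given condition at an adjusted p under 0.05. The highest numbers were in minimal medium at the transition point (1636 genes, 828 higher and 808 lower in the mutant) and in rich medium in stationary phase (2047, 984 higher and 1063 lower). The other 7 conditions gave 104 to 264 genes each. This order held in the shared fit of all 36 libraries. When only the 4 libraries of a comparison were fitted, minimal log (861) exceeded minimal transition (773) and LIV log gave 442, so minimal transition no longer stood apart, while rich stationary stayed highest (1313). With every library thinned to the smallest total, the other 7 conditions gave 66 to 165 genes. Over all 9 conditions 2983 genes (69.1% of those tested) were called at least once, or 2765 with adjustment over all 9 tests at once. Of the 2983, 2132 were called in no condition other than minimal transition and rich stationary, 851 (19.7% of genes tested) in at least 1 of the other 7, and 753 were higher in one condition and lower in another. Opposite calls lay mostly between minimal transition and rich stationary (546 genes). The next highest pair, LIV log and rich stationary, had 129. 3 genes were called in all 9 conditions: lrp and ompT, an outer membrane protease, were lower each time, and lysU, a lysyl-tRNA synthetase, was higher each time. fimA and fimI of the type 1 fimbriae, gltB of glutamate synthase and ilvI of acetohydroxy acid synthase III were lower in 8 of 9. Of 252 pairs of a fixed gene list and a condition, 99 passed a set test with a preset correlation between genes, and 19 of those also with an estimated correlation. A call in one condition and none in another is not by itself a difference between conditions, which the interaction tests at the end address.

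**Figure D2:**
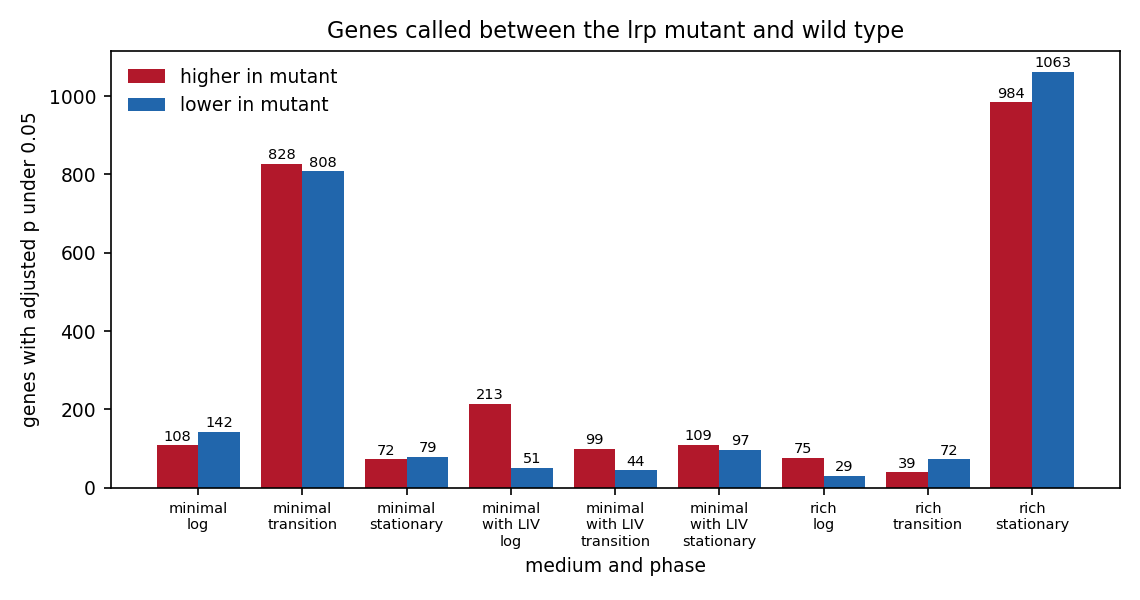
Genes with adjusted p under 0.05 between mutant and wild type (vertical axis, number of genes) in each medium and phase, n = 2 libraries per strain, red bars higher and blue bars lower in the mutant. Minimal transition (828 and 808) and rich stationary (984 and 1063) stand above the other 7 conditions.

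Averaged over the 9 conditions, the mutant had higher lysU (log2 fold change 3.21 ± 0.12, SE, n = 18 libraries per strain), livJ, the periplasmic binding protein for branched-chain amino acids (2.56 ± 0.21), the tripeptide permease dtpB (2.04 ± 0.07) and the multidrug exporter emrD (1.89 ± 0.09). The SE and p-values of the average rest on the spread between libraries within groups. They do not measure how far a change differed between conditions. Further high genes were the small RNA isrC (2.87 ± 0.35) and flu, encoding antigen 43 (2.41 ± 0.44). It had lower fimA, the major subunit of type 1 fimbriae (-3.58 ± 0.10), ompT (-2.97 ± 0.11), the glutamate synthase genes gltB (-2.94 ± 0.14) and gltD (-2.77 ± 0.18), and patA, a putrescine aminotransferase (-2.82 ± 0.08). Of branched-chain amino acid synthesis, ilvI (-2.46 ± 0.13), ilvH (-2.01 ± 0.15) and the leucine operon leader leuL (-2.55 ± 0.25) were also low. serA, the first enzyme of serine synthesis, stood at -1.55 ± 0.08, the homoserine exporter rhtB at -1.51 ± 0.11, the nucleoid protein gene stpA at -1.46 ± 0.16 and the fimbrial usher fimD at -2.02 ± 0.09. The largest adjusted p of these genes was 2.4e-04, for flu. Of 51 measured flagella and chemotaxis genes 41 rose (43 adjusted over the list alone), with fliC, the flagellin, at 0.82 ± 0.09 and flgK at 0.57 ± 0.07, and the list passed with adjusted p = 1.6e-24 and 7.4e-05 with an estimated correlation. This average was carried by rich log and LIV log, without which the values of fliC and of flgK sum to below 0, and by LIV transition; fliC was called higher in 3 conditions and lower in 2. Of 9 type 1 fimbriae genes 8 fell (8 fell and 1 rose adjusted over the list alone). The fimbrial list gave adjusted p = 5.4e-12 in the set test, and 8.2e-04 with an estimated correlation. Glutamate and ammonia assimilation fell in 8 of 10 genes and rose in 1, with the same counts adjusted over the list alone. Tested as a set, nitrogen assimilation had adjusted p = 4.9e-06, and adjusted p = 0.13 with an estimated correlation.

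The average test called 1264 genes, 632 in each direction, 93 of them over 2-fold. With the 7 conditions other than minimal transition and rich stationary, chosen after the data were seen, it called 406 (220 higher, 186 lower). The ammonium channel gene amtB, at -0.79 ± 0.13 over all 9 conditions, was at 0.068 there (adjusted p = 0.86), and the nitrogen regulator gene nac went from -1.07 ± 0.14 to -0.39 (adjusted p = 0.13), ddpX from -1.91 ± 0.23 to -0.59 (0.17), hisA from 0.66 ± 0.10 to 0.25 (0.17) and thrA from 1.23 ± 0.13 to 0.38 (0.11). trxB, at 0.21 (0.13), and the ribosomal gene rplC, at 0.26 (0.25), were not called there either, so these calls rested on the 2 conditions left out.

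**Figure D3:**
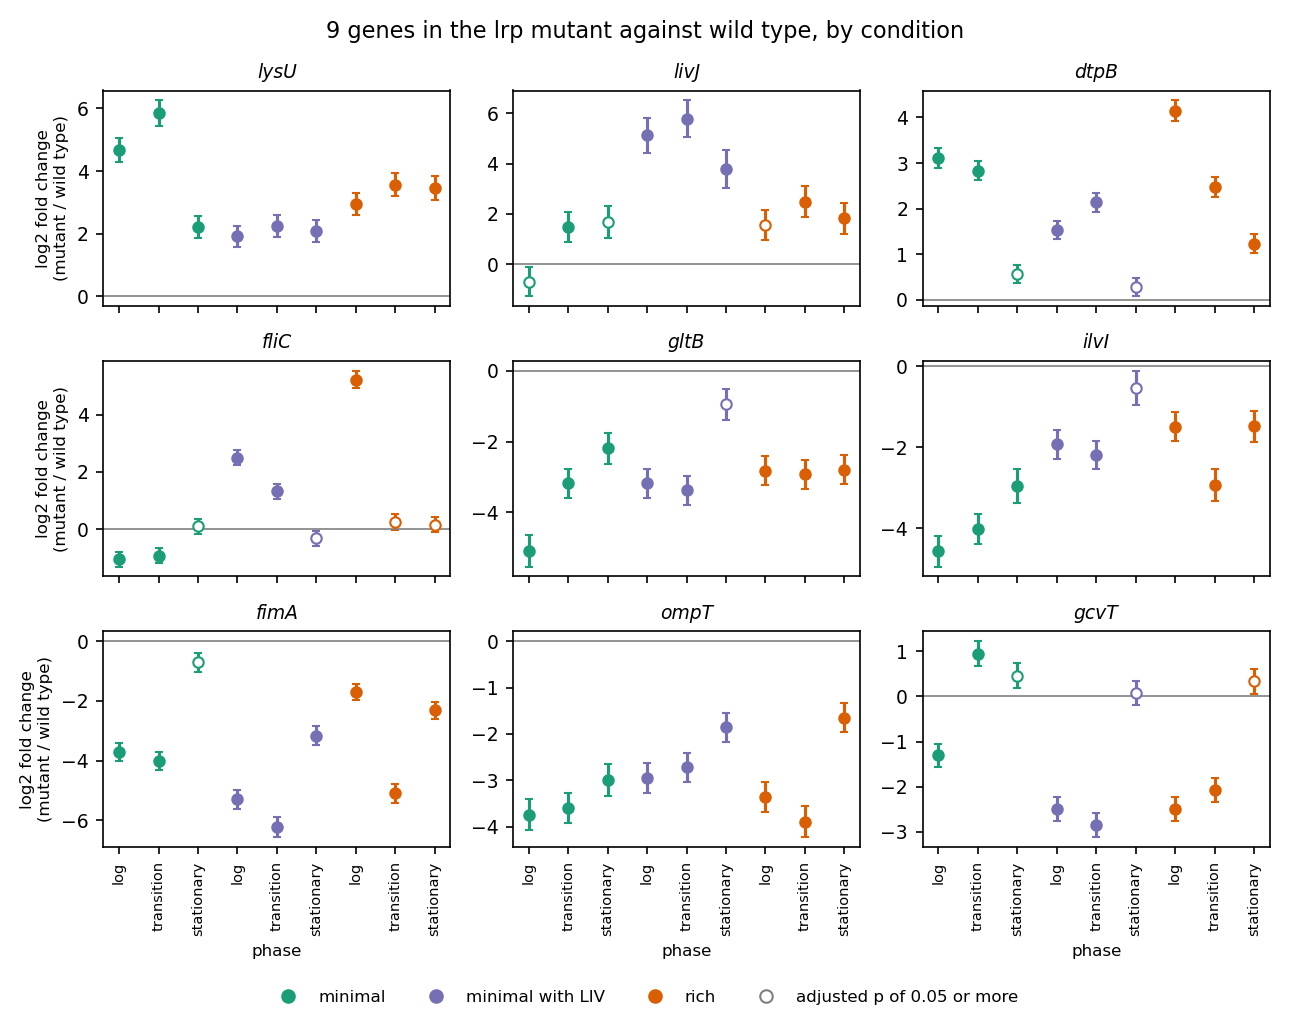
Log2 fold change, mutant over wild type, of 9 genes (vertical axes) in the 9 conditions (horizontal axes by phase, coloured by medium), with bars for 1 SE, n = 2 libraries per strain, and open symbols at adjusted p of 0.05 or more. lysU lies above 0 and ompT below 0 in all 9, while fliC and gcvT were called in both directions.

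**Figure D4:**
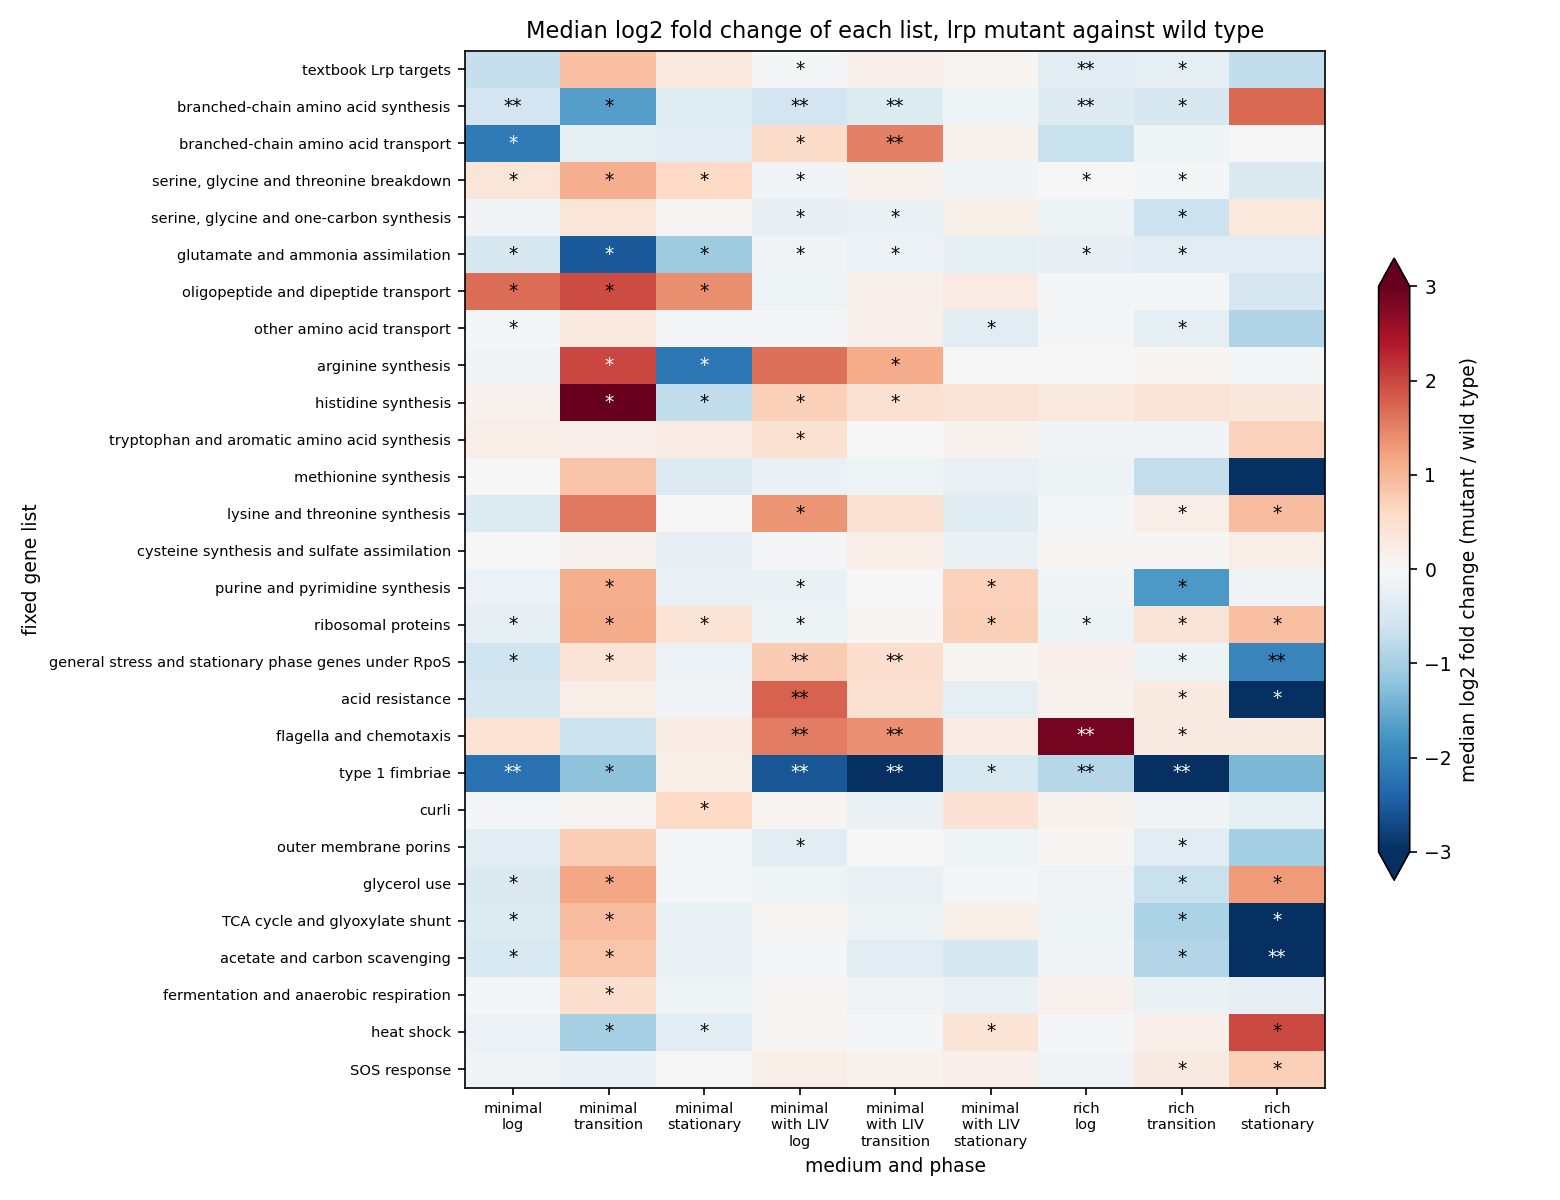
Median log2 fold change, mutant over wild type (colour), of each fixed gene list (rows) in each condition (columns). A single star marks adjusted p under 0.05 in the set test with a preset correlation and a double star also with an estimated one, reached by 19 of the 99 starred cells.

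In minimal medium in log phase (n = 2 libraries per strain, as in every condition that follows) the mutant had fewer transcripts of glutamate synthase, branched-chain synthesis and fimbriae and more of peptide transport. gltB (-5.08 ± 0.45, log2 fold change with SE), gltD (-4.77 ± 0.54), ilvI (-4.57 ± 0.38), ilvH (-4.34 ± 0.44), patA (-4.16 ± 0.25) and the transporter gene yhjE (-4.05 ± 0.42) were among the genes that fell most, each with adjusted p of 1.4e-06 or less. The di- and tripeptide permease dtpA (4.97 ± 0.50) and lysU (4.67 ± 0.39) rose, calls that held with any library left out. Of 13 branched-chain synthesis genes 6 fell and none rose, with the same counts adjusted over the list alone, leuA (-2.87 ± 0.22) and leuD (-2.40 ± 0.27) among them. Branched-chain synthesis gave adjusted p = 1.5e-09 in the set test, and 0.0088 with an estimated correlation. Of 10 branched-chain transport genes 5 fell, with livH at -4.64 ± 0.42 and livK at -3.88 ± 0.46, and 2 rose, both counts alike adjusted over the list alone. The set test for branched-chain transport gave adjusted p = 0.012, and adjusted p = 0.22 with an estimated correlation. Type 1 fimbriae fell in 7 of 9 genes (8 adjusted over the list alone), fimA at -3.71 ± 0.29 and fimI at -3.73 ± 0.37. The fimbrial list gave adjusted p = 1.6e-11 in the set test, and 0.0019 with an estimated correlation. Peptide transport rose in 10 of 20 (12 adjusted over the list alone), with dtpB at 3.12 ± 0.22 and oppB at 3.49 ± 0.52. As a set, peptide transport had adjusted p = 3.9e-12, and adjusted p = 0.071 with an estimated correlation. Of 36 RpoS-dependent stress genes 12 fell (20 adjusted over the list alone, where 1 rose), tktB at -1.09 ± 0.18. The RpoS list gave adjusted p = 1.4e-09 in the set test, and adjusted p = 0.071 with an estimated correlation. Among textbook Lrp targets the threonine breakdown genes kbl (2.52 ± 0.21) and tdh (2.27 ± 0.23) rose, and stpA (-3.46 ± 0.37), serA (-2.50 ± 0.24) and ompT (-3.74 ± 0.33) fell.

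The test called 250 genes in that condition, 108 higher and 142 lower. With the replicate block shared by the strains, the zinc genes zinT and znuA were not called. Among the highest, zinT of zinc uptake (5.99 ± 1.0) and its partner znuA (4.0 ± 0.70) lost the call without mutant replicate 2 (adjusted p = 0.6 and 0.57), and isrC (5.58 ± 1.23) and flu (5.25 ± 1.47) did so without any of several single libraries (wild type replicate 1 or wild type replicate 2 for isrC, any of the 4 for flu; highest adjusted p = 0.13 and 0.27). The count was 113 without wild type replicate 2 or mutant replicate 2, 127 without mutant replicate 1, 148 without wild type replicate 1 and 861 when only the 4 libraries of the comparison were fitted.

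In minimal medium at the transition point several single genes known from nitrogen limitation were far lower in the mutant. amtB (-8.31 ± 0.48), nac (-6.86 ± 0.39), the signalling protein gene glnK (-9.86 ± 0.77), the dipeptidase gene ddpX (-8.13 ± 0.52) and astC (-8.18 ± 0.92) and astA (-6.39 ± 0.77) of arginine breakdown fell, together with the glutamine transport genes glnP (-2.80 ± 0.21) and glnH (-2.77 ± 0.22) and leuL (-6.34 ± 0.81). Of 10 glutamate and ammonia assimilation genes 8 fell and 1 rose, with the same counts adjusted over the list alone. With all members tested together, nitrogen assimilation had adjusted p = 2.5e-05, and adjusted p = 0.17 with an estimated correlation. The oligopeptide permease genes oppB (6.54 ± 0.63), oppC (5.0 ± 0.54) and oppD (4.22 ± 0.54), lysU (5.85 ± 0.42) and the arginine transport genes artQ (4.20 ± 0.33) and artJ (4.08 ± 0.73) rose, and 17 of 20 peptide transport genes rose (17 adjusted over the list alone, where 1 fell). Peptide transport gave adjusted p = 6.2e-09 in the set test, and adjusted p = 0.17 with an estimated correlation. Of 54 ribosomal protein genes 47 rose and 1 fell (48 and 2 adjusted over the list alone), rplD by 3.50 ± 0.39 and rplC by 3.35 ± 0.39. In the set test ribosomal proteins had adjusted p = 8.6e-18, and adjusted p = 0.2 with an estimated correlation. All 8 histidine synthesis genes rose, also adjusted over the list alone, with hisA at 3.46 ± 0.29 (adjusted p = 4.3e-09; adjusted p = 0.13 with an estimated correlation), and so did 12 of 14 glycerol use genes on both counts, glpF at 2.32 ± 0.36. Glycerol use gave adjusted p = 6.6e-05 in the set test, and adjusted p = 0.13 with an estimated correlation. Of 17 heat shock genes 13 fell (15 adjusted over the list alone), with ibpB at -3.01 ± 0.46, dnaK at -1.73 ± 0.28 and htpX at -1.45 ± 0.15. As a set, heat shock had adjusted p = 1.5e-06, and adjusted p = 0.2 with an estimated correlation. fimA (-4.01 ± 0.30), ilvI (-4.02 ± 0.38), serA (-2.78 ± 0.24) and stpA (-5.41 ± 0.43) fell here as well, and kbl (2.45 ± 0.21), the catalase gene katE (3.40 ± 0.29) and ftsK (2.62 ± 0.14) rose. Every gene named in this paragraph had an adjusted p of 1.2e-04 or less, and 1636 genes were called, 773 when only the 4 libraries of the comparison were fitted.

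In stationary minimal cultures the efflux genes alaE, an alanine exporter (4.42 ± 0.70), and emrD (2.91 ± 0.25), the transporter gene yqeG (2.75 ± 0.34) and the peptide-binding genes oppA (3.39 ± 0.56) and dppA (2.71 ± 0.45) rose. patA (-3.37 ± 0.24), ompT (-3.0 ± 0.34) and ilvI (-2.95 ± 0.42) fell, and lysU rose by 2.22 ± 0.36; these 9 genes had adjusted p of 0.0013 or less. Arginine synthesis fell in 5 of 11 genes (7 adjusted over the list alone; adjusted p = 1.1e-05; adjusted p = 0.51 with an estimated correlation), and this list was lost without wild type replicate 2 (adjusted p = 0.19). Its members argA (-3.68 ± 0.80) and argC (-4.47 ± 0.99) lost their calls without wild type replicate 2, mutant replicate 1 or mutant replicate 2 (highest adjusted p = 0.3 and 0.4); argI and argF also passed, but share reads with each other. Peptide transport rose in 7 of 20 and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 9.4e-04; adjusted p = 0.51 with an estimated correlation), lost without wild type replicate 2 (adjusted p = 0.063), as was oppB (3.17 ± 0.55; 0.054). leuL (-3.45 ± 0.65) was lost without mutant replicate 1 (adjusted p = 0.068) and isrC (5.23 ± 1.14) without wild type replicate 1, wild type replicate 2 or mutant replicate 2 (highest adjusted p = 0.14). The test called 151 genes, 72 higher and 79 lower, and 85, 66, 50 and 28 without wild type replicates 1 and 2 and mutant replicates 1 and 2. DESeq2 called 257, and 23 were called when only the 4 libraries of the comparison were fitted, where argA and argC were not called (adjusted p = 0.16 and 0.15). argA was not called with the replicate block shared by the strains either.

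With LIV in log phase the mutant had more flagellar, acid resistance and stress transcripts and fewer fimbrial ones. Of 51 flagella and chemotaxis genes 37 rose (45 adjusted over the list alone), fliC by 2.50 ± 0.27, the cap protein gene fliD by 2.09 ± 0.26 and flgK by 1.58 ± 0.19. The flagellar list gave adjusted p = 7.2e-35 in the set test, and 6.2e-06 with an estimated correlation. Type 1 fimbriae fell in 7 of 9 (8 adjusted over the list alone), fimA at -5.29 ± 0.32, fimI at -5.23 ± 0.41 and fimD at -3.53 ± 0.28. Tested as a set, the fimbrial list had adjusted p = 5.1e-22, and 1.5e-05 with an estimated correlation. RpoS-dependent genes rose in 17 of 36 (24 adjusted over the list alone), with yciF at 1.70 ± 0.23, the trehalose synthesis gene otsA at 1.10 ± 0.17 and tktB at 1.16 ± 0.18. The RpoS list gave adjusted p = 1.4e-20 in the set test, and 0.0029 with an estimated correlation. Acid resistance rose in 14 of 19 (15 adjusted over the list alone), with hdeD at 1.76 ± 0.29 (adjusted p = 5.9e-19, and 0.0099 with an estimated correlation); gadA (3.27 ± 0.53) shares its reads with gadB and is uncertain. Branched-chain synthesis fell in 6 of 13 genes on both counts, over all genes and adjusted over the list alone, leuA at -1.83 ± 0.22 and ilvI at -1.93 ± 0.36. The set test for branched-chain synthesis gave adjusted p = 4.0e-06, and 0.027 with an estimated correlation. livJ rose by 5.13 ± 0.69 and dtpB by 1.53 ± 0.20, and the glycine cleavage genes gcvT (-2.50 ± 0.26), gcvH (-2.28 ± 0.26) and gcvP (-2.01 ± 0.23), with serA (-2.29 ± 0.24), gltB (-3.18 ± 0.41), gltD (-3.03 ± 0.50), ompT (-2.95 ± 0.32) and alaE (-5.03 ± 0.64), fell. The test called 264 genes, 213 higher and 51 lower, and 131 without wild type replicate 1, 89 without wild type replicate 2 and 165 without mutant replicate 1, or 442 with only the 4 libraries of the comparison. flu (5.31 ± 1.48) and isrC (4.84 ± 1.09) were lost without wild type replicate 1 or wild type replicate 2 (highest adjusted p = 0.26 and 0.12), and flu also without either mutant library.

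With LIV at the transition point fimbrial transcripts were lower in the mutant and flagellar ones higher. fimA stood at -6.23 ± 0.33, fimC, the fimbrial chaperone gene, at -6.51 ± 0.37 and fimD at -5.54 ± 0.28, with 7 of 9 type 1 fimbriae genes lower (8 adjusted over the list alone). The fimbrial list gave adjusted p = 1.6e-32 in the set test, and 1.6e-06 with an estimated correlation. Flagella and chemotaxis rose in 20 of 51 genes (34 adjusted over the list alone), the flagellar sigma factor gene fliA by 3.78 ± 0.49, flgC by 3.85 ± 0.37, flgD by 3.09 ± 0.36 and flgE by 2.43 ± 0.31. As a set, the flagellar list had adjusted p = 6.2e-26, and 2.7e-05 with an estimated correlation. Branched-chain transport rose in 5 of 10 genes (7 adjusted over the list alone), livJ by 5.78 ± 0.73 (adjusted p = 4.6e-07, and 0.0064 with an estimated correlation), while branched-chain synthesis fell in 6 of 13 on both counts, adjusted over the list alone included, leuA at -1.82 ± 0.22 and ilvI at -2.20 ± 0.35. Branched-chain synthesis gave adjusted p = 4.6e-07 in the set test, and 0.018 with an estimated correlation. RpoS-dependent genes rose in 5 of 36 (13 adjusted over the list alone), yciF by 1.67 ± 0.24. With all members tested together, the RpoS list had adjusted p = 3.3e-11, and 0.026 with an estimated correlation. The uracil permease gene uraA (2.47 ± 0.31), the biotin synthase gene bioB (2.34 ± 0.42), the dimethyl sulfoxide reductase gene dmsA (2.21 ± 0.32), dtpB (2.14 ± 0.20) and lysU (2.25 ± 0.35) rose. The molybdate transport genes modA (-4.69 ± 0.66) and modB (-3.76 ± 0.49), yghW (-6.21 ± 0.68), alaE (-5.36 ± 0.67), gcvP (-2.66 ± 0.24), gcvT (-2.85 ± 0.27), gltB (-3.37 ± 0.41), serA (-2.09 ± 0.23) and ompT (-2.72 ± 0.32) fell. The test called 143 genes, 99 higher and 44 lower, and 84 without mutant replicate 1. With every library thinned to the smallest total the count was 76 and bioB was not called (adjusted p = 0.055). At full depth bioB had the largest adjusted p of the named genes, 9.0e-04.

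In stationary LIV cultures, among calls that held with any library left out, guaB of guanine nucleotide synthesis (2.96 ± 0.46) and the purine repressor gene purR (2.13 ± 0.35) were higher, and lower were fimA (-3.16 ± 0.31), patA (-3.11 ± 0.24), yqeC (-2.60 ± 0.32) and sgcQ (-2.14 ± 0.28), all 6 with adjusted p of 0.0016 or less. Purine and pyrimidine synthesis rose in 7 of 21 genes (10 adjusted over the list alone; adjusted p = 5.7e-06; adjusted p = 0.53 with an estimated correlation); its member purE had 0 and 1 counts in wild type, so no fold is given. Ribosomal protein genes rose in 10 of 54 (29 adjusted over the list alone). Ribosomal proteins gave adjusted p = 1.4e-16 in the set test, and adjusted p = 0.53 with an estimated correlation. Type 1 fimbriae fell in 2 of 9 (3 adjusted over the list alone). In the set test the fimbrial list had adjusted p = 0.0022, and adjusted p = 0.45 with an estimated correlation. lysU (2.08 ± 0.35), livJ (3.79 ± 0.75) and ompT (-1.86 ± 0.32) kept the direction of the average, but lysU was lost without wild type replicate 1 (adjusted p = 0.089), livJ without wild type replicate 1 or mutant replicate 2 (highest adjusted p = 0.14) and ompT without mutant replicate 2 (adjusted p = 0.075). Of 206 genes called, 109 higher and 97 lower, 13 were called without wild type replicate 1, 16 without mutant replicate 2 and 331 without wild type replicate 2. DESeq2 called 369, and 11 were called when only the 4 libraries of the comparison were fitted, where guaB (adjusted p = 0.070), purR (0.068), sgcQ (0.15) and ompT (0.051) were not called.

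In rich medium in log phase nearly the whole flagellar list was higher in the mutant. Of 51 flagella and chemotaxis genes 49 rose (51 adjusted over the list alone; adjusted p = 2.2e-205, and 1.7e-12 with an estimated correlation), among them fliC (5.22 ± 0.31), fliD (4.48 ± 0.27), flgK (3.90 ± 0.21), the chemoreceptor genes tar (5.41 ± 0.42) and tsr (4.46 ± 0.25) and the chemotaxis kinase gene cheA (4.42 ± 0.40). flxA of the Qin prophage rose by 5.71 ± 0.43, dtpB by 4.15 ± 0.23 and lysU by 2.94 ± 0.36. Lower genes were ompT (-3.35 ± 0.32), the putrescine transport gene potG (-3.04 ± 0.32), gltD (-2.87 ± 0.51), gltB (-2.83 ± 0.41) and gcvT (-2.49 ± 0.27), with gcvP at -2.15 ± 0.24, gcvH at -2.31 ± 0.26 and serA at -1.33 ± 0.23. Branched-chain synthesis fell in 5 of 13 genes (6 adjusted over the list alone), leuA at -2.22 ± 0.24 and leuB at -1.91 ± 0.32. Branched-chain synthesis gave adjusted p = 1.4e-08 in the set test, and 0.0085 with an estimated correlation. Of 33 textbook Lrp targets 8 fell and 1 rose (12 and 3 adjusted over the list alone; adjusted p = 3.8e-06, and 0.0085 with an estimated correlation); 29 of the 33 are also in other lists. Type 1 fimbriae fell in 4 of 9 (5 adjusted over the list alone), fimA at -1.71 ± 0.27. As a set, the fimbrial list had adjusted p = 5.3e-06, and 0.015 with an estimated correlation. The test called 104 genes, 75 higher and 29 lower, and the largest adjusted p of the genes above was 5.9e-04, for gltD. isrC (4.68 ± 1.07) lost its call without wild type replicate 1 or wild type replicate 2 (highest adjusted p = 0.21) and potH (-2.40 ± 0.47) without mutant replicate 2 (0.055).

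In rich medium at the transition point transcripts of several purine synthesis genes and of type 1 fimbriae were lower in the mutant. purT (-4.48 ± 0.36), purK (-3.11 ± 0.49), purD (-2.77 ± 0.33) and purM (-2.76 ± 0.40) fell, with 10 of 21 purine and pyrimidine synthesis genes lower (14 fell and 1 rose adjusted over the list alone). Nucleotide synthesis gave adjusted p = 9.7e-12 in the set test, and adjusted p = 0.063 with an estimated correlation. Type 1 fimbriae fell in 7 of 9 genes (adjusted over the list alone 7 fell and 1 rose), fimA at -5.09 ± 0.31, fimI at -4.58 ± 0.47 and fimD at -3.70 ± 0.28. Tested as a set, the fimbrial list had adjusted p = 1.2e-15, and 2.6e-04 with an estimated correlation. ompT (-3.89 ± 0.33), ilvI (-2.94 ± 0.39), gltB (-2.92 ± 0.41), serA (-2.09 ± 0.24), gcvT (-2.07 ± 0.26) and gcvP (-1.90 ± 0.23) fell, and lysU (3.57 ± 0.37), dtpB (2.48 ± 0.21) and ftsK (1.09 ± 0.14) rose. Of the textbook targets 2 rose and 8 fell (2 and 11 adjusted over the list alone). The textbook list gave adjusted p = 1.3e-04 in the set test, and adjusted p = 0.052 with an estimated correlation. TCA cycle genes fell in 7 of 21 (14 adjusted over the list alone). The set test for the TCA list gave adjusted p = 3.5e-13, and adjusted p = 0.13 with an estimated correlation. The test called 111 genes, 39 higher and 72 lower, and the largest adjusted p of the genes so far was 3.5e-04, for purK. livJ (2.48 ± 0.62) lost its call without any 1 of the 4 libraries, wild type replicate 1, wild type replicate 2, mutant replicate 1 or mutant replicate 2 (highest adjusted p = 0.17), bioD (2.51 ± 0.53) without wild type replicate 1 or mutant replicate 1 (0.099) and the xanthine permease gene xanP (-3.25 ± 0.70) without mutant replicate 2 (0.15). Without mutant replicate 2 the count was 73. DESeq2 called 205, and 18 were called when only the 4 libraries of the comparison were fitted, where dtpB, ftsK, serA, gcvP, gltB, bioD and xanP were not called (adjusted p = 0.057 to 0.28). livJ was not called with the replicate block shared by the strains.

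In rich medium in stationary phase genes of stress defence, acid resistance and acetate and sugar scavenging were far lower in the mutant. Of 36 RpoS-dependent genes 32 fell and 1 rose, with the same counts adjusted over the list alone, tktB at -3.16 ± 0.20, talA at -3.14 ± 0.22 and yciE at -3.18 ± 0.22. The RpoS list gave adjusted p = 1.9e-13 in the set test, and 0.044 with an estimated correlation. Acetate and carbon scavenging fell in 16 of 20 genes (17 adjusted over the list alone), the ribose permease gene rbsC at -4.73 ± 0.38 and the pyruvate oxidase gene poxB at -2.62 ± 0.21. As a set, the scavenging list had adjusted p = 4.8e-09, and 0.044 with an estimated correlation. Acid resistance fell in 17 of 19 and rose in 1, alike adjusted over the list alone, hdeB at -6.51 ± 0.49 and hdeA at -6.30 ± 0.48. Acid resistance gave adjusted p = 7.7e-10 in the set test, and adjusted p = 0.13 with an estimated correlation. TCA and glyoxylate genes fell in 18 of 21 and rose in 1, alike adjusted over the list alone, aceK at -5.85 ± 0.39 and aceA at -5.89 ± 0.45. With all members tested together, the TCA list had adjusted p = 2.8e-09, and adjusted p = 0.26 with an estimated correlation. Heat shock genes rose in 16 of 17 (17 adjusted over the list alone), the protease genes hslU by 2.90 ± 0.21 and lon by 2.77 ± 0.21 and the small chaperone gene ibpB by 4.43 ± 0.51. Heat shock gave adjusted p = 1.8e-09 in the set test, and adjusted p = 0.16 with an estimated correlation. Ribosomal protein genes rose in 36 of 54 (37 adjusted over the list alone), rplO by 1.90 ± 0.23. In the set test ribosomal proteins had adjusted p = 8.7e-08, and adjusted p = 0.53 with an estimated correlation. Of 13 branched-chain synthesis genes 8 rose, leuA by 2.49 ± 0.24 and ilvE by 4.04 ± 0.42, and 4 fell, ilvC at -2.97 ± 0.31 (8 and 5 adjusted over the list alone; adjusted p = 0.12), so that leuA ran against its average.

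Among the lowest single genes there were the tryptophanase operon genes tnaA (-9.62 ± 0.68) and tnaB (-9.66 ± 0.71) and glcE of glycolate use (-8.06 ± 0.77); tnaC had 0 counts in both mutant libraries and yjcH 1 and 2, so no fold is given. Among the higher genes were the threonine synthesis gene thrA (6.73 ± 0.49), the small RNA gcvB (6.34 ± 0.51), psiE (5.22 ± 0.56), the RNA helicase gene deaD (4.57 ± 0.27) and the osmolyte transporter gene proP (3.58 ± 0.19), with thrB at 4.34 ± 0.42. lysU (3.45 ± 0.37) rose and fimA (-2.32 ± 0.28), gltB (-2.79 ± 0.41) and ompT (-1.65 ± 0.31) fell as in the average, each gene so far in this paragraph with adjusted p of 1.2e-04 or less. Methionine synthesis fell in 8 of 10 genes (10 adjusted over the list alone) without passing the set test (adjusted p = 0.062), and metF (-8.04 ± 1.59) lost its call without wild type replicate 2 (adjusted p = 0.47). The test called 2047 genes, 984 higher and 1063 lower, and 1313 with only the 4 libraries of the comparison. Wild type replicate 1 was the smallest library of all, and the pair had the lowest replicate correlation.

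Among wild type cultures, LIV in log phase lowered the genes of branched-chain amino acid supply and raised serine and threonine breakdown. ilvC, the acetohydroxy acid isomeroreductase gene (-6.57 ± 0.36), livJ (-7.06 ± 0.75), livK (-6.31 ± 0.53), livH (-6.13 ± 0.45) and leuA (-3.12 ± 0.22) fell. gcvB (6.95 ± 0.52), alaE (7.56 ± 0.78), the alanine racemase gene dadX (3.28 ± 0.52), yqeG (3.28 ± 0.32) and dtpA (3.25 ± 0.47) rose, with adjusted p of 1.4e-04 or less for these 10. Branched-chain synthesis fell in 11 of 13 genes on both counts, adjusted over the list alone included (adjusted p = 1.1e-27, and 1.3e-05 with an estimated correlation), and branched-chain transport in 6 of 10 with 1 rising (6 and 2 adjusted over the list alone). Branched-chain transport gave adjusted p = 3.4e-10 in the set test, and 9.1e-04 with an estimated correlation. Flagella and chemotaxis fell in 40 of 51 (47 adjusted over the list alone), fliC at -3.15 ± 0.28. As a set, the flagellar list had adjusted p = 8.6e-52, and 3.0e-07 with an estimated correlation. Serine, glycine and threonine breakdown rose in 8 of 14 on both counts, adjusted over the list alone included, kbl by 2.07 ± 0.21 and sdaB by 2.25 ± 0.31. The breakdown list gave adjusted p = 4.2e-12 in the set test, and 0.0041 with an estimated correlation. The test called 190 genes, 77 higher and 113 lower, and 785 with only the 4 libraries of the comparison.

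At the transition point 2393 wild type genes differed between LIV and minimal medium (1129 higher, 1264 lower). Whether cultures of different media were in a like growth state at the transition point or in stationary phase was not tested, here or for rich medium. astC (-10.17 ± 1.02), amtB (-9.82 ± 0.52), nac (-8.18 ± 0.42), ddpX (-8.18 ± 0.52) and livK (-6.12 ± 0.55) fell, and gcvB (8.20 ± 0.55), the glycerol phosphate transporter gene glpT (6.82 ± 0.30), oppB (6.35 ± 0.62) and gcvP (4.59 ± 0.27) rose. All 14 glycerol use genes rose, also adjusted over the list alone, with glpF at 4.82 ± 0.40. Tested as a set, glycerol use had adjusted p = 2.0e-09, and 0.0061 with an estimated correlation. In stationary phase 673 genes differed (352 higher, 321 lower), alaE at 5.97 ± 0.72, gcvB at 3.81 ± 0.50, rbsD at 3.0 ± 0.50 and argA at -4.31 ± 0.84. That count was 141 without wild type minimal stationary replicate 2, 216 without wild type LIV stationary replicate 1 and 134 with only the 4 libraries of the comparison, and argA lost its call without wild type minimal stationary replicate 2 (adjusted p = 0.13).

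Rich against minimal medium in log phase changed 2477 wild type genes (1267 higher, 1210 lower). The pyruvate transporter gene yjiY (8.58 ± 0.25), gcvB (6.81 ± 0.51), dtpA (5.50 ± 0.52), emrD (5.37 ± 0.30), the serine deaminase gene sdaB (4.87 ± 0.34) and the malate oxidoreductase gene mqo (4.73 ± 0.36) rose. katE (-7.12 ± 0.35), the ribosome hibernation gene rmf (-6.96 ± 0.51), thiE of thiamine synthesis (-6.96 ± 0.38), leuA (-4.61 ± 0.24) and fliC (-3.43 ± 0.28) fell, all 11 with adjusted p of 7.1e-09 or less. RpoS-dependent genes fell in 35 of 36 on both counts, adjusted over the list alone included (adjusted p = 1.7e-24, and 0.0031 with an estimated correlation), and flagella in 44 of 51, alike adjusted over the list alone. The flagellar list gave adjusted p = 4.8e-08 in the set test, and 0.022 with an estimated correlation. All 54 ribosomal protein genes rose, also adjusted over the list alone. The set test for ribosomal proteins gave adjusted p = 4.1e-18, and adjusted p = 0.23 with an estimated correlation. At the transition point 2136 genes differed (1059 higher, 1077 lower), with amtB at -10.10 ± 0.53, nac at -8.33 ± 0.43, oppB at 6.50 ± 0.63, gcvB at 6.47 ± 0.51, the tryptophan transporter gene mtr at 6.09 ± 0.28 and all 14 glycerol use genes higher, also adjusted over the list alone. Glycerol use gave adjusted p = 1.1e-10 in the set test, and 0.0027 with an estimated correlation. In stationary phase 2186 differed (1142 higher, 1044 lower), with waaH at 10.29 ± 0.66, tnaA at 8.83 ± 0.66, ilvC at 5.64 ± 0.36, dppA at 4.41 ± 0.48, the ribonucleotide reductase gene nrdE at -4.53 ± 0.47 and prpB of propionate use at -6.47 ± 0.80, and 1396 with only the 4 libraries of the comparison.

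Across growth phases of the wild type, the transition point in minimal medium raised amtB and nac and lowered many genes of nucleotide synthesis and of ribosomal proteins. Against log phase, amtB rose by 10.05 ± 0.52, nac by 8.46 ± 0.42, the zinc genes ykgM by 9.70 ± 0.73 and zinT by 8.72 ± 1.12, and carA (-7.43 ± 0.85), uraA (-5.99 ± 0.37), the galactose transport gene mglA (-6.97 ± 0.64) and glpT (-5.94 ± 0.29) fell. Nucleotide synthesis fell in 20 of 21 genes, alike adjusted over the list alone. The set test for nucleotide synthesis gave adjusted p = 7.0e-11, and adjusted p = 0.08 with an estimated correlation. Flagella fell in 41 of 51 genes, alike adjusted over the list alone, flgE at -4.64 ± 0.35 (adjusted p = 1.2e-09, and 0.02 with an estimated correlation), and ribosomal proteins in 51 of 54 with 1 rising (52 and 1 adjusted over the list alone). As a set, ribosomal proteins had adjusted p = 1.2e-19, and adjusted p = 0.21 with an estimated correlation. In stationary phase pyrB (-10.50 ± 0.85), pyrI (-9.65 ± 0.74) and trpE (-7.90 ± 0.65) fell and the small RNA gene ryjA (8.59 ± 0.47), the biofilm regulator gene bssR (7.75 ± 0.55) and otsA (3.07 ± 0.18) rose. Glycerol use fell in 13 of 14, alike adjusted over the list alone. Glycerol use gave adjusted p = 1.2e-06 in the set test, and 0.027 with an estimated correlation. The calls numbered 2589 at the transition point (1362 higher, 1227 lower) and 2891 in stationary phase (1446 higher, 1445 lower).

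With LIV, 1626 genes differed at the transition point (772 higher, 854 lower) and 3013 in stationary phase (1533 higher, 1480 lower). Fermentation and anaerobic respiration rose at the transition point in 27 of 30 genes (28 adjusted over the list alone), the hydrogenase gene hybO by 5.63 ± 0.38 and the fumarate reductase gene frdB by 2.51 ± 0.17. With all members tested together, the fermentation list had adjusted p = 6.7e-20, and 6.1e-04 with an estimated correlation. zinT (10.94 ± 1.20), the porin gene ompW (7.55 ± 0.64) and the asparaginase gene ansB (6.34 ± 0.46) rose, and sodA, the manganese superoxide dismutase gene (-6.14 ± 0.33), and fhuF of iron uptake (-5.62 ± 0.44) fell. In stationary phase pyrB (-10.68 ± 0.87) and the glutamine synthetase gene glnA (-7.62 ± 0.60) fell, and ryjA (9.07 ± 0.48), bssR (8.87 ± 0.58) and prpB (8.65 ± 0.75) rose. In rich medium 2877 genes differed at the transition point (1411 higher, 1466 lower) and 2955 in stationary phase (1508 higher, 1447 lower). At the transition point the acid resistance genes gadC (11.13 ± 0.71) and gadE (10.43 ± 0.77), zinT (10.99 ± 1.20) and wrbA (8.34 ± 0.30) rose, and yjiY (-8.24 ± 0.25), sodA (-6.26 ± 0.33), bioA (-6.33 ± 0.39) and the putrescine importer gene plaP (-6.20 ± 0.30) fell. RpoS-dependent genes rose in 34 of 36 there and in all 36 in stationary phase, on both counts adjusted over the list alone included (adjusted p = 1.5e-20 and 1.7e-18; 0.0085 and 0.014 with an estimated correlation), with bssR at 12.74 ± 0.69 and otsA at 6.11 ± 0.21 in stationary phase. Ribosomal protein genes fell in 54 of 54 at both, also adjusted over the list alone (adjusted p = 8.2e-21 and 3.5e-21; adjusted p = 0.23 and 0.23 with an estimated correlation).

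The strain difference itself differed between media for many genes. The LIV and rich comparisons of a phase share the minimal medium libraries of that phase, so their counts are not separate evidence. In log phase the difference with LIV exceeded that in minimal medium for fliC (3.54 ± 0.37, a difference of log2 fold changes with SE over 8 libraries), livH (5.23 ± 0.65), tktB (2.25 ± 0.26), yciE (2.12 ± 0.25) and the aldehyde dehydrogenase gene aldB (2.28 ± 0.30), and lay below it for alaE (-7.89 ± 1.01), yqeG (-3.52 ± 0.41), the protease inhibitor gene eco (-3.41 ± 0.27) and kbl (-2.22 ± 0.29). 330 genes were called (240 positive, 90 negative), 173 without wild type minimal log replicate 2, 216 without mutant minimal log replicate 2, 204 without wild type LIV log replicate 2 and 747 with only the 8 libraries of the comparison. RpoS-dependent genes were positive in 20 of 36 (25 adjusted over the list alone; adjusted p = 9.5e-23, and 0.0034 with an estimated correlation) and flagella in 20 of 51 (25 adjusted over the list alone). The flagellar list gave adjusted p = 7.2e-12 in the set test, and 0.0034 with an estimated correlation. Serine, glycine and threonine breakdown was negative in 5 of 14 (8 adjusted over the list alone). In the set test the breakdown list had adjusted p = 2.6e-08, and 0.031 with an estimated correlation. At the transition point 1053 genes were called (527 positive, 526 negative), with amtB (8.23 ± 0.58), nac (6.60 ± 0.51) and patA (4.77 ± 0.33) positive and gcvP (-4.39 ± 0.34), fimD (-4.39 ± 0.38) and ftsK (-1.95 ± 0.19) negative, and 645 with only the 8 libraries. Flagella were positive in 25 of 51 (27 adjusted over the list alone). The flagellar list gave adjusted p = 8.4e-10 in the set test, and 0.016 with an estimated correlation. In stationary phase 84 were called (47 positive, 37 negative), emrD at -2.38 ± 0.33 and alaE at -5.90 ± 0.88, a count that ran from 3 without mutant LIV stationary replicate 2 to 170 without wild type minimal stationary replicate 1. It was 4 and 27 without wild type minimal stationary replicate 2 and mutant minimal stationary replicate 1, 41 without mutant minimal stationary replicate 2, 8 and 129 without wild type LIV stationary replicates 1 and 2 and 150 without mutant LIV stationary replicate 1, with 232 by DESeq2 and 10 from the 8 libraries alone.

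For rich against minimal medium, the log phase difference was positive in 44 of 51 flagella and chemotaxis genes (48 adjusted over the list alone; adjusted p = 4.5e-82, and 6.8e-09 with an estimated correlation), with fliC at 6.25 ± 0.39, tsr at 5.21 ± 0.33 and flgK at 4.05 ± 0.28. patA (4.43 ± 0.36) and fimA (2.0 ± 0.38) were positive too, and dtpA (-5.49 ± 0.64), yqeG (-3.86 ± 0.41), kbl (-2.28 ± 0.29) and mtr (-2.37 ± 0.34) negative. 132 genes were called there (97 positive, 35 negative), and 373 with only the 8 libraries. At the transition point 1029 were called (478 positive, 551 negative), with amtB (8.13 ± 0.60), patA (4.06 ± 0.33) and the ppGpp synthase gene relA (2.70 ± 0.18) positive and gcvP (-3.63 ± 0.34), purT (-5.49 ± 0.52), katE (-3.87 ± 0.38) and artQ (-4.11 ± 0.42) negative. Glycerol use was negative in 10 of 14 (12 adjusted over the list alone). As a set, glycerol use had adjusted p = 4.8e-07, and 0.033 with an estimated correlation. In stationary phase 1446 were called (624 positive, 822 negative). proP (3.68 ± 0.25), aroG of aromatic amino acid synthesis (3.64 ± 0.26), thrA (6.74 ± 0.61) and hslU (3.44 ± 0.28) were positive, and the autoinducer genes lsrK (-5.01 ± 0.28), lsrA (-6.57 ± 0.44) and lsrB (-6.94 ± 0.47) with aldB (-5.37 ± 0.33) negative. Only the 8 libraries of each comparison gave 337 and 937.

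Tested across the 3 phases within a medium, the strain difference changed for 1241 genes in minimal medium, 154 with LIV and 1571 in rich medium. Among the 8 smallest p-values in minimal medium were those of amtB (adjusted p = 5.5e-10), relA (2.8e-09), nac (6.5e-09), ddpX (1.7e-08) and ftsK (8.9e-08). With LIV they included fimD (2.9e-08), gcvP (7.4e-05), gcvT (1.2e-04), gcvH (1.6e-04) and serA (2.2e-04), and in rich medium lsrK (7.0e-12), proP (8.4e-11), aldB (3.2e-10) and flgK (1.1e-09). The LIV count was 63 and 54 without wild type LIV log replicates 1 and 2, 47 without wild type LIV stationary replicate 1, 63 and 84 without mutant LIV transition replicates 1 and 2 and 37 without mutant LIV stationary replicate 2, and DESeq2 called 346.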

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

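The thinning was chosen after the counts it bears on had been seen. Leaving out libraries was planned before, but its use as a test here, with its limit, was set after. The other tests of this part were written before. The strain difference changed with the medium or the phase for many genes, by a test of the difference itself (edgeR, adjusted p under 0.05), which is what singled out the 9 counts that follow. Against minimal medium it differed with LIV for 330 genes in log phase, 1053 at the transition point and 84 in stationary phase. Against minimal medium it differed in rich medium for 132, 1029 and 1446 genes in the same phases. Over the 3 phases it differed for 1241 genes in minimal medium, 154 with LIV and 1571 in rich medium. Minimal transition enters both transition counts and the 1241, and rich stationary enters the 1446 and the 1571. These counts are thus not separate evidence. The stationary LIV count of 84 was 3 without mutant LIV stationary replicate 2 and 170 without wild type minimal stationary replicate 1, and the 154 was 37 without mutant LIV stationary replicate 2. Genes with small p-values are given with the comparisons.

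The widest strain difference in minimal medium lay at the transition point, with 1636 genes against 250 and 151 in the other phases, in the fit of all 36 libraries. With only the 4 libraries of each comparison fitted, log phase (861) overtook the transition point (773), with 23 in stationary phase. That fit has fewer degrees of freedom and its own spread, and which of these changed the order was not tested. The tests that follow apply to the shared fit. Unequal depth is argued against as its cause, since with every library thinned to the smallest total 1224 genes were called, against at most 165 in the 7 conditions other than this and rich stationary. An earlier way of thinning, replaced after its counts had been seen, gave 483 against at most 64. A single deviating library was argued against as well, since at least 1206 genes were called with any 1 of the 4 libraries left out. A mutant culture sampled earlier on the wild type course could give such a pattern, and then nearly all called genes would lie between the wild type log and transition levels; 50.7% of 1635 did, and 34.7% lay between the transition and stationary levels. If genes change in 1 direction between log phase and the transition point, the 50.7% argues against an earlier sample as the whole cause. No allowance was made for error in the fitted levels, and a gene could count in both shares. An earlier sample as part of the cause stays open. A difference in growth state between the strains, which is a biological one, was not tested and stays open.

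Rich medium in stationary phase gave 2047 genes. Thinning left 1708 (866 by the earlier way) and the lowest count with 1 library left out was 1647, which argues against depth and against 1 deviating library, although wild type replicate 1 was the smallest library and its pair the least alike. Of 2046 called genes 18.5% had a mutant level between the wild type transition and stationary levels. If genes change in 1 direction between those points, that argues against a sample taken between them as the whole cause. Error in the fitted levels was not allowed for here either, and such a sample as part of the cause stays open. Levels between log phase and the transition point were not tested, so a still earlier sample stays open. Other differences in the state of these cultures were not tested and remain open beside an effect of Lrp.

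For the average of the 9 conditions, 100 groupings of the libraries within conditions were fitted, the real one included. The real strains gave 1264 genes and the highest of the others 893, so of the 100 only the real 1 reached its count. With 100 groupings the smallest share possible is 1 of 100. The result argues against chance in the grouping of the libraries without excluding it. A regrouping that leaves the strains apart in most conditions still carries part of their difference, and one that mixes them adds that difference to the spread within groups.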

How the results depend on the processing

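Of the alternatives, only thinning, the culture number block for the average and the F tests and the counts without minimal transition and rich stationary were chosen after seeing the data. RLE size factors, no filter on low counts and removal of rRNA and tRNA genes left each of 33 counts within 1.5 times, and all 392 gene values named in the text kept their direction and call under these and under DESeq2. The named genes were picked mostly from the strongest calls of these data, so they say little about the other calls. Of 357 list calls over all comparisons 6 were lost with RLE and 8 without rRNA and tRNA genes, with adjusted p up to 0.060. The cause was not tested for the changes given here unless it is named.

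With every library thinned to 808193 counts, which leaves 3800 genes to test, the strain comparisons gave 165 genes in minimal log, 84 in minimal stationary, 159 in LIV log, 76 in LIV transition, 66 in LIV stationary and 69 in rich log, and the average 834. The counts for minimal transition, rich transition and rich stationary and the union over conditions stayed within 1.5 times, and 6 of 251 gene values lost their call: argC in minimal stationary, isrC in LIV log and rich log, bioB in LIV transition, potH in rich log and bioD in rich transition. A first sampler, replaced after its counts had been seen because its draws were too variable, gave 15 to 64 genes in the 7 conditions other than minimal transition (483) and rich stationary (866), and 400 for the average. An estimated correlation left 19 of 99 list calls between the strains and 50 of 357 over all comparisons. Leaving out minimal transition and rich stationary gave 406 genes for the average and 851 for the union, and turned the average of amtB to 0.068 on the log2 scale, with 6 of 28 gene values losing their call.

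DESeq2 called 257 genes in minimal stationary, 369 in LIV stationary, 205 in rich transition, 232 for the strain difference with LIV against minimal in stationary phase and 346 across phases with LIV. The other 27 of its 32 counts stayed within 1.5 times. A fit of only the libraries compared, which has fewer degrees of freedom and its own spread, called 861 genes between the strains in minimal log, 773 in minimal transition, 23 in minimal stationary, 442 in LIV log, 11 in LIV stationary, 18 in rich transition and 1313 in rich stationary. For wild type media it called 785 (LIV against minimal, log), 134 (LIV against minimal, stationary) and 1396 (rich against minimal, stationary). For the strain difference against minimal medium it called 747, 645 and 10 with LIV and 373, 337 and 937 in rich medium, in log, transition and stationary order. Minimal log thus overtook minimal transition in that fit, where 13 of 364 gene values lost their call and none turned: argA and argC in minimal stationary, guaB, purR, sgcQ and ompT in LIV stationary and bioD, dtpB, xanP, ftsK, serA, gcvP and gltB in rich transition.

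Whether equal replicate numbers mark paired samples was not settled, and the main fits took no pairing. Most same-numbered libraries of the 2 strains carried adjacent culture numbers. Deviations of same-numbered libraries correlated between the strains with r of -0.03 to 0.30, above 0.1 in 4 of 9 pairs, and in 4 of 12 between media and 4 of 12 between phases. With the replicate number as a block, the strain difference with LIV against minimal in stationary phase was called for 131 genes, and the other 20 counts of that block, 12 of the blocks shared by media or phases and 7 with a culture number block stayed within 1.5 times. The block shared by the strains lost 4 of 306 gene values: zinT and znuA in minimal log, argA in minimal stationary and livJ in rich transition, and 6 of 184 list calls (adjusted p up to 0.065), and the block shared by the phases 1 of 91 (0.057).

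With 1 library left out at a time, the strain comparisons gave 113 to 148 genes in minimal log, 1206 to 1473 in minimal transition, 28 to 85 in minimal stationary, 89 to 190 in LIV log, 84 to 123 in LIV transition, 13 to 331 in LIV stationary, 86 to 92 in rich log, 73 to 142 in rich transition, 1647 to 1858 in rich stationary and 1154 to 1336 for the average, and 91 to 105 list calls. LIV against minimal in wild type gave 134 to 151, 1898 to 2098 and 141 to 690 in log, transition and stationary phase, and rich against minimal 2063 to 2147, 1764 to 1860 and 1871 to 1930. Against log phase, the transition point gave 2161 to 2243 in minimal medium, 1127 to 1273 with LIV and 2563 to 2609 in rich medium, and stationary phase 2594 to 2655, 2735 to 2801 and 2556 to 2745. The strain difference against minimal medium gave 173 to 264, 753 to 1005 and 3 to 170 with LIV and 90 to 112, 745 to 993 and 1152 to 1414 in rich medium. Across phases it gave 905 to 1216 in minimal medium, 37 to 198 with LIV and 1236 to 1644 in rich medium. Of 2740 gene values 41 lost their call and none turned. Of 5300 list values 287 lost theirs and 1 turned, acid resistance in rich transition without wild type replicate 1, at adjusted p = 0.811. Its adjusted p ran from 2.1e-04 to 0.995 over the libraries left out, so this list call was not stable. A lone library left in a group was assumed to vary like the other groups.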

Other observations

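In minimal medium other amino acid genes also differed between the strains. In log phase serine, glycine and threonine breakdown rose in 5 of 14 genes and fell in 3, alike adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.22 with an estimated correlation). The serine deaminase gene sdaB stood at 2.65 ± 0.31, the serine transporter gene sdaC at 2.76 ± 0.43 and gcvP at -1.38 ± 0.23. Other amino acid transport rose in 9 of 35 genes and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0085; adjusted p = 0.37 with an estimated correlation), with mtr at 2.47 ± 0.24, the tyrosine permease gene tyrP at 1.45 ± 0.20 and artI of arginine transport at 1.64 ± 0.26. The median of that list was -0.05 and its mean 0.28, so they differed in sign and the rise was that of some members. At the transition point the breakdown list rose in 9 of 14 genes and none fell, alike adjusted over the list alone (adjusted p = 3.8e-04; adjusted p = 0.18 with an estimated correlation), with tdh at 1.96 ± 0.23 and gcvP at 1.73 ± 0.24. Fermentation and anaerobic respiration rose there in 10 of 30, alike adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.22 with an estimated correlation), with frdA at 1.8 ± 0.22 and dmsB at 1.81 ± 0.33. Of nucleotide synthesis genes, purB (2.54 ± 0.35) and purF (1.66 ± 0.27) were higher and pyrB (-3.72 ± 0.65) and pyrI (-3.79 ± 0.56) lower.

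In rich stationary cultures 11 of 19 SOS response genes rose and 1 fell, alike adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.19 with an estimated correlation), with the helicase gene uvrD at 1.73 ± 0.18, recA at 1.01 ± 0.15 and sbmC at -1.27 ± 0.21. Lysine and threonine synthesis rose in 6 of 11 genes and fell in 1, alike adjusted over the list alone (adjusted p = 0.0086; adjusted p = 0.19 with an estimated correlation), a call lost without wild type replicate 2 (adjusted p = 0.068), with thrC at 4.19 ± 0.41 and dapA at 0.92 ± 0.16. The tyrosine synthesis genes tyrA (-3.46 ± 0.32) and aroF (-4.47 ± 0.38) passed in that condition too, as did the serine protease subunit gene clpP (1.98 ± 0.17), the outer membrane fatty acid transporter gene fadL (-4.03 ± 0.46) and the C4-dicarboxylate transporter gene dctA (-2.99 ± 0.27). On the average of the 9 conditions, acetate and carbon scavenging fell in 16 of 20 genes, alike adjusted over the list alone (adjusted p = 1.5e-07; adjusted p = 0.06 with an estimated correlation), and all 8 histidine synthesis genes rose, alike adjusted over the list alone (adjusted p = 5.0e-06; adjusted p = 0.19 with an estimated correlation). Ribosomal protein genes rose in 47 of 54 (52 adjusted over the list alone; adjusted p = 2.7e-17; adjusted p = 0.19 with an estimated correlation), with rplC at 0.73 ± 0.12. Minimal transition and rich stationary carried the calls of rplC and hisA in these averages: without them rplC stood at 0.26 (adjusted p = 0.25) and hisA of histidine synthesis at 0.25 (0.17), and neither was called.

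The genes next to lrp were higher in the mutant: ftsK by 1.05 ± 0.05 and rarA by 0.88 ± 0.06 on the average of the 9 conditions (log2, SE). A candidate explanation is that transcription from the kanR insertion ran into the genes that follow lrp. It predicts that lolA, which lies between ftsK and rarA, is higher too, and lolA was higher by 0.67 ± 0.08 (log2, adjusted p = 8.1e-07), in a test fixed before its value was seen. As the genes on both sides of lolA were higher, its rise could also come from an effect of Lrp on this stretch, so it does not tell these apart. The next gene, serS, stood at 0.37 ± 0.05 with adjusted p = 1.8e-05. trxB and cydC on the other side of lrp stood at 0.34 ± 0.07 and 0.38 ± 0.08, with cydD between them at 0.26 ± 0.10 and not called (adjusted p = 0.068), and dmsA, beyond serS, at 0.46 ± 0.12, so smaller rises were also found where such transcription was not tested. rarA, serS, cydC, cydD and dmsA were taken here after their values were seen. An effect of Lrp itself on these genes, which the strains also differ in, stays open and was not tested.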
